A study of Mus musculus with 4 samples.

How the data were processed

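Gene expression was measured in basal epidermal cells of mouse embryos at E16.5, sorted by flow cytometry on α6 integrin and on YFP. Of the 4 samples, 2 came from embryos labelled cKO, in which both Srf alleles were floxed and K14-Cre was present. The other 2 came from embryos labelled het, with 1 floxed allele and the same Cre and YFP reporter, which the submitters' design text calls wild type. Each group held a sample whose title has the number 1210 (het_1210, Ko_1210), called the first pair, and a sample whose title has the number 1261 (het_1261, KO_1261), called the second pair. No label says what these numbers mark, nor whether samples came from separate embryos or from pools. The spread between these samples may thus be in part technical, and the p-values draw on it only in part. Which part of Srf is floxed is not given in the sources used here.

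Total RNA was extracted with Trizol and labelled with biotin by a 3' in vitro transcription kit, per the labels' protocols. The deposited values are array intensity values on a linear scale, 1 per probe set and array, made by the authors with MAS5, per the submitters' processing notes. The version of MAS5 is not given in the sources used here. MAS5 combines the probes of a probe set and corrects for background. On all 4 arrays the mean of the deposited intensity values, with 2% of the probe sets trimmed at each end, was 500, so the arrays had been scaled to a common mean and only changes relative to that mean can be seen. MAS5 signals near background are noisy on a log scale, so a difference from or into background is imprecise. The median signal was 69.3 in het_1210, 82.5 in het_1261, 63.7 in Ko_1210 and 75.5 in KO_1261. For arrays, the number of samples, 2 per group, limits the precision.

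The table held 45101 probe sets, of which 64 controls were left out of the tests. Gene names came from the platform annotation, updated through the Entrez gene identifier: 34945 probe sets had 1 gene symbol (34741 of them matched by identifier), 932 had several and 9160 had none. Probe sets with several symbols or none stayed in the fit and were given no gene name. No genome build was used and no coordinates are given. A gene was represented by its probe set with the highest mean signal over the 4 arrays.

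Values were transformed as log2(signal + 1) with no further scaling, so fold changes are on that scale. Probe sets above the median of the mean log2 signal (a signal of 65.9) were tested: 22518 probe sets, which represent 11055 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. This fit had no block and 2 residual degrees of freedom. Lists of genes, 24 for pathways and epidermal layers and 9 of markers of other cell types, were fixed before the data were examined: 549 of their 588 memberships matched a gene on the array, and the 31 lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, and beside it with the estimated correlation and with fry. The estimated correlation and fry draw on the few residual degrees of freedom of the fit, so these 2 tests had little power. A list that did not pass them is not shown to be unmoved. At the preset correlation the genes of a list count as nearly independent, so that p-value does not measure the spread between arrays. Values of signal are given as mean ± SD with n = 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

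The numbers 1210 and 1261 separated the arrays technically. The poly-A spike-in controls, which are added to the RNA before labelling, were 2.41-fold higher in number 1210 than in number 1261 in het and 2.56-fold higher in cKO, at 12 of 12 probe sets, and the hybridization spike-ins were 1.99-fold and 1.73-fold higher, at 9 of 9. The cKO to het ratio of these controls was 0.918 and 0.865 for poly-A and 0.78 and 0.898 for hybridization spike-ins, in 1210 and 1261. This was seen before any model was fitted. The deviations from the group means of same-numbered arrays correlated at 0.755 across probe sets. With 2 pairs and no label, the numbers are not shown to pair animals. They were treated as a batch that holds both groups, and the fit without a block is therefore set beside a fit with the number as a block (an alternative planned before the data were examined) and, for many genes and lists, beside the difference within each number, which has 1 array per group and no test. The fit with the block had 1 residual degree of freedom per probe set and relied on a common variance with 34.4 prior degrees of freedom, against 3.01 without the block. It can therefore pass a gene on its mean difference even where only 1 of the numbers moved.

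The pipeline was tested on simulated data built from the real means, the real difference between the numbers and the fitted variances of the 22518 tested probe sets. In these data 200 genes were changed, and a further list of genes was lowered by a smaller amount. For cKO against het without the block, 0 of 50 genes were recovered at a log2 change of 1, -1, 2 and -2. With the block, 42 and 39 of 50 were recovered at 1 and -1, and 50 and 44 of 50 at 2 and -2, with 6 calls among 22295 unchanged probe sets. Of the 50 genes each changed by -1 and -2, 49 and 45 lay above the filter and could be recovered. The simulation draws every probe set's spread around the fitted variance, which favours the fit with the block.

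Named genes followed a rule fixed before the data were examined. It took Srf and, for the strongest changes, the 10 genes with the largest rise and the 10 with the largest fall. Apart from Srf, these had to pass with both cKO arrays beyond both het arrays in that direction. Where fewer than 10 did so, the rest were filled by the smallest unadjusted p. Predicted genes without a proper symbol were skipped. The rule also took up to 4 members of each list by smallest p, from which examples are given, and 20 genes always reported. Applying the part for the strongest changes to the fit with the block was added after the data were seen. Genes named outside these rules were chosen after their values were seen, as is said where they appear. Alternatives covered the block, scaling (quantile, median centring), a pseudocount of 32, filters, the variance model, each array left out, the choice of probe set, and the list test. The same choices combined with the block were added after the data were seen. All 4 columns of the table were used.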

Results

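Expression arrays compared sorted basal epidermal cells from mouse embryos at E16.5 with a conditional deletion of Srf (cKO, n = 2) and with 1 floxed Srf allele (het, n = 2). Srf encodes serum response factor, a transcription factor that works with the actin-regulated MRTF coactivators on cytoskeletal genes and with ternary complex factors on immediate early genes. The series' title places the comparison in the differentiation of the embryonic epidermis. The sample titles carry numbers that recur in both groups: het_1210 and Ko_1210 are called the first pair, and het_1261 and KO_1261 the second pair, although no label says that the numbers pair animals. All differences below are cKO minus het on the log2 scale, with the standard error of the limma fit that has the number as a block. That standard error draws mostly on a variance shared across probe sets, so it can be smaller than the spread between the pairs. For Egr2 it was 0.29, while the differences within the pairs were -1.76 and -4.08. A bracket with a pair of values gives the difference within the first pair and then within the second.

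Srf itself was lower in both cKO samples. The brighter Srf probe set had a signal of 971 ± 194 in het and 64.1 ± 23.0 in cKO (SD, n = 2), a 15.3-fold difference, with a log2 difference of -3.93 ± 0.26 (-4.09 and -3.77). The other Srf probe set went from 221.9 ± 10.6 to 31.0 ± 17.5, a difference of -2.92 ± 0.47. Whether these probe sets lie within the floxed part is not known here, so they check the labels only as far as the transcript was lost. In limma without a block Srf had the smallest p among the genes that fell, unadjusted p = 2.03e-04, and did not pass adjustment. With the block it passed (adjusted p = 1.18e-12), though not when the variance trend was left out (0.169).

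Without a block, 0 of 11055 genes and 0 of 22518 probe sets passed in limma, and 66 genes and 108 probe sets had an unadjusted p under 0.05. With the number as a block, 96 genes passed, 28 higher and 68 lower in cKO, and 194 probe sets passed, 82 higher and 112 lower. Of the 96 genes, 27 of the 28 higher and 67 of the 68 lower had the same sign within both pairs, and 11 higher and 39 lower exceeded 1.5-fold within both. Genes were called on the mean of these 2 differences, so a shared sign is favoured by the selection and is no separate check. These calls rest on the variance model: 0 genes passed with the block when the prior variance was not allowed to follow the signal, and 50 with a robust prior. Median centring with the block changed the balance to 30 higher and 22 lower, because it moved the median difference of all tested genes from -0.02 to 0.10. Below, rose and fell are used of genes that passed with the block, and no gene named passed without it when all 4 arrays were used. Independent of any variance estimate, 81 genes (7 higher, 74 lower) differed by more than 1.5-fold in all 4 ratios of a cKO to a het array, and 50 (17 higher, 33 lower) after median centring. The other 2 ways to split the 4 arrays gave 956 genes for the second against the first pair and 38 for the crossed split.

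Among the immediate early genes, which respond within minutes to growth factors and stress, the Egr zinc finger transcription factors fell while several others rose. Egr2 fell by 2.92 ± 0.29 (-1.76 and -4.08), Egr1 fell by 2.13 ± 0.17 (-1.49 and -2.76) and Egr3 fell by 1.80 ± 0.21 (-1.52 and -2.08). The signal of Egr3 was 1068 ± 30.1 in het and 310.7 ± 74.9 in cKO (SD, n = 2). Of the 18 tested members of the list, 3 fell and 5 rose. Adjusted over the list alone, 4 fell and 7 rose. The genes that rose did so mainly within the first pair: Dusp1, a MAP kinase phosphatase, differed by 1.46 ± 0.24 (2.65 and 0.26), Zfp36 by 1.37 (2.51 and 0.22), Jun by 1.26 (2.29 and 0.23), Atf3 by 1.14 (2.02 and 0.25) and Ier3 by 0.78 (1.25 and 0.30). Apart from Dusp1, these were named after their values were seen. Fos, with a difference of 0.44 ± 0.16 (1.07 and -0.18), did not pass. The calls of Egr1 and Egr2 and of these 5 genes ended with the robust prior (adjusted p = 0.606 for Egr1 and 0.736 for Egr2), where that of Egr3 held (1.31e-06). The list as a whole did not pass: its median was 0.29 (0.52 and 0.05), camera adjusted p = 0.878, and 0.0814 with the block. With 1 array left out the median ranged from -0.90 without het_1210 to 1.53 without het_1261, and the list passed in each case, since the pairs were then unbalanced between the groups.

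**Figure D1:**
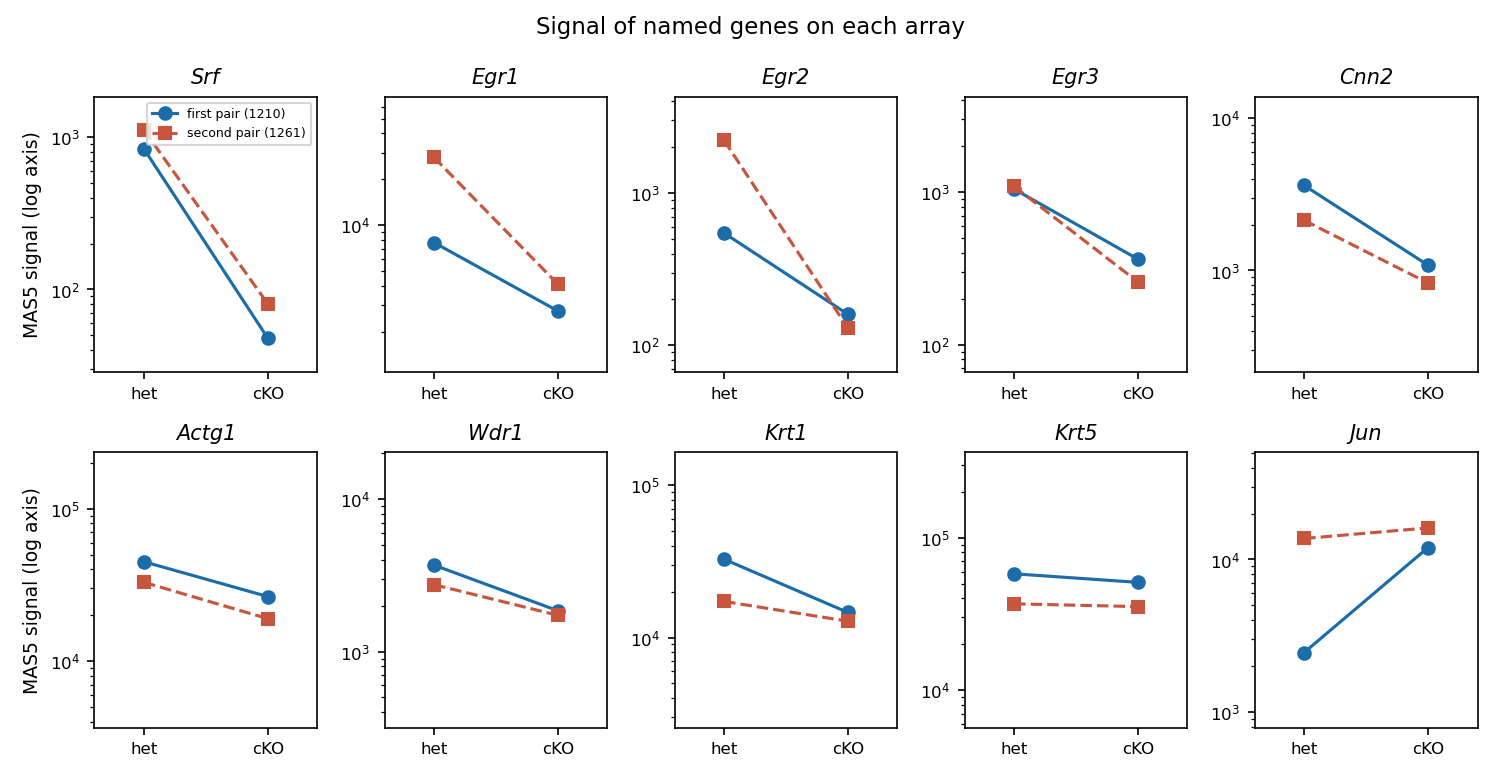
MAS5 signal (log axis, each panel spanning the same fold range) of 10 genes on the 4 arrays, with lines joining the het and cKO array of the first pair (circles, solid) and of the second pair (squares, dashed); each point is 1 array, so no error is drawn. Srf, Egr1, Egr2, Egr3, Cnn2, Actg1, Wdr1 and Krt1 were lower in cKO within both pairs, Krt5 differed by -0.12 on the log2 scale, and Jun was higher by 2.29 in the first pair and by 0.23 in the second.

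Of 34 tested MRTF-SRF target genes, 28 were lower in cKO, with a median of -0.22 (-0.15 and -0.20). Median centring gave 22 of 34 and a median of -0.095, but it also moved the median of all tested genes from -0.02 to 0.10. The list moved up with all tested genes, so this does not show a weaker shift relative to them. Calponin 2 (Cnn2) fell by 1.55 ± 0.17 (-1.74 and -1.36), with a signal of 2871 ± 1046 in het and 956 ± 181 in cKO (SD, n = 2). Wdr1, which promotes disassembly of actin filaments with cofilin, fell by 0.83 ± 0.16 (-0.99 and -0.67), cytoplasmic γ-actin (Actg1) fell by 0.78 ± 0.12 (-0.76 and -0.79), filamin A (Flna) fell by 0.74 ± 0.15 (-0.63 and -0.85) and β-actin (Actb) fell by 0.63 ± 0.13 (-0.91 and -0.34). The control probe sets for Actb were 1.97-fold (3' end), 2.31-fold (5' end) and 2.25-fold (middle) higher in het, while those for Gapdh differed by 1.05-fold to 1.07-fold. The Actg1 probe set may also read transcripts of related actins. These 5 genes passed with the block over all genes, and 8 of the list when adjusted over the list alone. Vinculin (Vcl) at -0.56 ± 0.17 (-0.18 and -0.94), cofilin 1 (Cfl1) at -0.13 ± 0.12 and Myl9 at -0.67 ± 0.40 (-1.80 and 0.47) did not pass.

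The MRTF-SRF list passed with camera at the preset correlation (adjusted p = 9.85e-06 without and 3.58e-07 with the block). These p-values take the genes of the list as nearly independent and do not measure the spread between arrays. The list did not pass with an estimated correlation (adjusted p = 0.674 without and 0.752 with the block), nor without het_1261 (adjusted p = 0.109). Fblim1, which links filamin to cell adhesions, fell by 2.26 ± 0.34 (-1.88 and -2.64, with a KO_1261 signal of 52.1, below the filter). Csrp1, an actin-bundling LIM protein named after its values were seen, fell by 0.81 ± 0.17 (-0.85 and -0.77). Of 14 tested microtubule genes, 10 were lower and 4 higher, and the list did not pass (camera adjusted p = 0.283, and 0.168 with the block). Its members Tubb6, at -0.71 ± 0.17, and Tubb2b, at -1.03 ± 0.24, fell, while Map1b, at 0.89 ± 0.30 (0.89 and 0.90), did not pass. The wider list of actin filament assembly and turnover did not pass (camera adjusted p = 0.283, and 0.0999 with the block). It had 24 of 34 genes lower and a median of -0.12 (-0.16 and -0.05), and of its members only Wdr1 passed. Its median became 0.003 under median centring, which raised the median of all tested genes as well. Markers of dermal fibroblasts were lower in the same samples, as given below.

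Of the epidermal layer genes, basal keratins and adhesion genes did not pass: Krt5 differed by -0.12 ± 0.12, Krt14 by -0.07 ± 0.12, with a sign that flipped under quantile scaling and median centring, Trp63 by 0.19 ± 0.14, Itga6 by 0.13 ± 0.15, Itgb1 by 0.25 ± 0.17 and Cdh1 by 0.01 ± 0.13. Of the 17 tested genes of the basal and basement membrane list 0 passed, and the list median was 0.09 (0.20 and -0.02; camera adjusted p = 0.386, and 0.396 with the block). Of 16 tested spinous genes, 9 were lower and 7 higher: Krt1 fell by 0.80 ± 0.14 (-1.16 and -0.43), Krt10 fell by 0.66 ± 0.13 (-0.90 and -0.42) and suprabasin (Sbsn) fell by 0.64 ± 0.15 (-0.86 and -0.42). These 3 were the spinous genes that passed; adjusted over the list alone, 5 fell and 1 rose. The spinous list median was -0.08 (-0.16 and -0.10), with camera adjusted p = 0.201 without the block and 0.0359 with it, and 0.752 with the block and an estimated correlation. Under median centring its median was 0.04, where that of all tested genes was 0.10.

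Of the 21 tested granular and cornified genes only Elovl4, an elongase of very long chain fatty acids, passed, and it fell by 1.12 ± 0.21 (-1.15 and -1.10). The list median was -0.12, with opposite signs within the pairs (0.10 and -0.47), and camera adjusted p was 0.386 without and 0.318 with the block. The median ranged from -0.39 without het_1210 to 0.35 without het_1261, and passed in both. Loricrin (Lor) differed by 0.47 ± 0.25 (1.68 and -0.75) and involucrin (Ivl) by 0.48 ± 0.34 (1.75 and -0.78). Filaggrin (Flg) lay below the filter and was not tested. Its signal was 39.3 and 144.0 on het_1210 and het_1261 and 3.62 and 11.2 on Ko_1210 and KO_1261. Lypd3, a membrane protein of suprabasal keratinocytes, fell by 1.06 ± 0.20 (-1.34 and -0.79). Ly6d, at -1.17 ± 0.16, and Calm4, at -0.67 ± 0.13, both named after their values were seen, also fell.

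**Figure D2:**
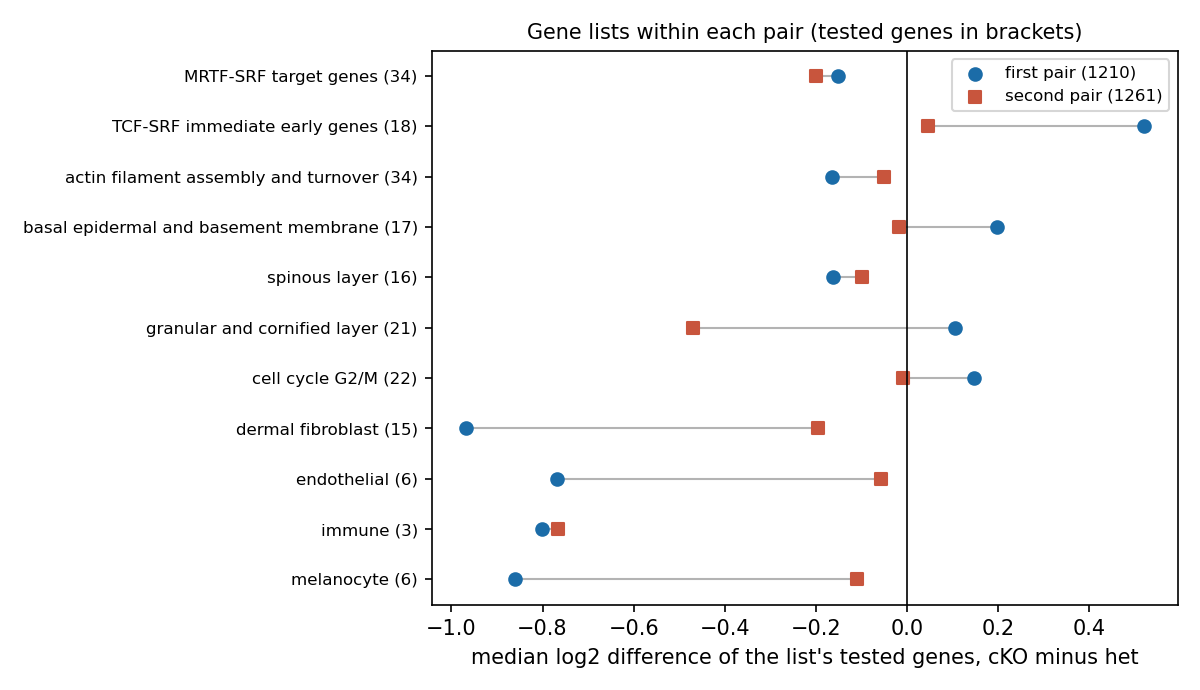
Median log2 difference (cKO minus het, horizontal axis) of the tested genes of 11 lists within the first pair (circles) and within the second pair (squares), with the number of tested genes in brackets; each point compares 1 cKO with 1 het array. The MRTF-SRF list was at -0.15 and -0.20, the granular list at 0.10 and -0.47, and dermal fibroblast markers at -0.97 and -0.20.

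Genes of the G2 and M phases of the cell cycle were slightly higher as a list, with 18 of 22 above 0 and a median of 0.07 (0.15 and -0.01). Camera gave an adjusted p of 0.0285, and 0.0313 with the block; with an estimated correlation it was 0.68, and with 1 array left out it ranged from 0.0636 to 0.745. None of the 22 passed singly (0 with the block). Top2a differed by 0.45 ± 0.14 and Mki67 by 0.05 ± 0.14. Of 12 tested wound keratins and alarmins, 5 were higher and 7 lower, and the list did not pass (camera adjusted p = 0.386, and 0.276 with the block). Adjusted over the list alone, 4 rose and 2 fell with the block. Over all genes 3 rose with the block, each mainly within 1 pair: Krt6b by 3.44 ± 0.50 (1.54 and 5.35, from het signals of 48.2 and 21.3 that lay below the filter), Krt6a by 1.32 ± 0.33 (0.02 and 2.63) and Sprr1b by 1.31 ± 0.33 (2.88 and -0.26). Krt6a and Krt6b are near-identical paralogs whose probe sets may read both, and all 3 calls ended with the robust prior. Il18, at -0.68 ± 0.39, did not pass. In the hair follicle placode list Lhx2, a transcription factor of follicle progenitors, fell by 1.21 ± 0.25 (-1.66 and -0.75), while Shh, at -0.54 ± 0.20, did not pass.

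Among the other genes with the strongest changes by the naming rule, the lower ones were Rpl39l (-1.54 ± 0.32) and Rpl39 (-1.22 ± 0.22), paralogs that could share probes, and, in the fit with the block, Msx3 (-2.55 ± 0.53) and Rhbdf2 (-2.24 ± 0.48), all 4 lower within both pairs. The signals of Msx3 in cKO (15.6 and 45.4) and of Rhbdf2 on Ko_1210 (20.0) lay below the filter, so the sizes of these falls are imprecise. Gas7 (-4.33 and -0.41), Pla2g2f (-4.09 and -0.43) and Prss22 (-0.02 and -3.44) fell mainly within 1 pair. On Ko_1210 the signals of Gas7 (9.06) and Pla2g2f (17.0) also lay below the filter. Gpihbp1, at -1.74 ± 0.48, did not pass in either fit. The higher genes that passed with the block, with both cKO arrays above both het arrays, were Fmod (1.29 ± 0.25), Acadl (0.87 ± 0.18), Hmga2 (0.87 ± 0.18), Mpdu1 (0.83 ± 0.18), Npnt (0.81 ± 0.18), Marveld1 (0.74 ± 0.15), Nfkbia (0.69 ± 0.16, with 1.31 and 0.08 within the pairs) and D17H6S56E-5 (0.65 ± 0.16). Krtap13 (2.16 ± 0.46), Pde4b (1.09 ± 0.19), Tnfaip3 (0.93 ± 0.18) and Ppp1r15a (0.90 ± 0.18), named after their values were seen, rose by more than Acadl. Their cKO and het arrays overlapped, so the naming rule left them out. Krtap13 rose mainly within the first pair (3.65 and 0.66), from a het_1210 signal of 6.12 that lay below the filter, so the size of its rise is imprecise. Other probe sets of Marveld1 and Npnt included 1 each of the opposite sign. Tacc1 (0.85 ± 0.23), Enox2 (0.90 ± 0.28) and Ppig (0.53 ± 0.16) did not pass, each had 1 other probe set of the opposite sign, and Tacc1 changed sign under quantile scaling, where its other probe set represented it. With the robust prior the calls of Gas7, Pla2g2f, Prss22, Npnt, Nfkbia and D17H6S56E-5 ended (adjusted p from 0.0715 for D17H6S56E-5 to 0.89 for Prss22).

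The sort on α6 integrin and YFP was meant to leave out other cell types, and some of their marker lists were lower in cKO. Of 15 tested dermal fibroblast markers 12 were lower, with a median of -0.62 (-0.97 and -0.20). The markers that fell were Col3a1 (-0.62 ± 0.15), Twist2 (-1.21 ± 0.31) and Vim (-0.71 ± 0.17), the last named after its values were seen, and 8 of the 15 fell when adjusted over the list alone. The calls of Col3a1, Twist2 and Vim ended with the robust prior. The abundant marker Dcn, also chosen afterwards, differed by 0.06 ± 0.12. Camera gave the list an adjusted p of 8.13e-07, 4e-07 with the block, 0.674 with an estimated correlation and 0.234 without Ko_1210. The medians of 3 immune and 6 melanocyte markers were -0.44 and -0.43 (both adjusted p = 0.0285, 0.0829 and 0.0814 with the block, and 0.674 with an estimated correlation). Neither list passed without Ko_1210 (0.464 and 0.154), the immune list did not pass without het_1261 (0.272), and the melanocyte list did not pass without het_1210 (0.908) or KO_1261 (0.0795). Laptm5, of the immune markers, fell by 1.47 ± 0.36 (-2.17 and -0.77), with 1 other probe set of the opposite sign and an adjusted p of 0.0682 with the robust prior. The 6 endothelial markers had a median of -0.33 (adjusted p = 0.0593, 0.228 with the block, and 0.0269 without KO_1261) and the 7 periderm markers -0.20 (0.527 and 0.400). The 4 skeletal muscle markers, at -0.04 (0.983 and 0.934), and the 3 nerve and Schwann cell markers, at 0.002 (0.878 and 0.636), did not pass either. Of the Merkel cell markers 2 were tested and of the erythroid markers 0, too few for a list test.

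In all, 5 of the 31 tested lists passed without a block, 1 higher and 4 lower, and 4 passed with it, 1 higher and 3 lower. With all arrays, 0 passed with an estimated correlation or by fry. With 2 residual degrees of freedom, and 1 with the block, these tests could hardly pass a list, so they do not decide. The p-values at the preset correlation do not measure the spread between arrays, so they do not decide either.

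RNA quality, read from the Gapdh control's 3' to 5' signal ratio, was 0.826 ± 0.063 in het and 0.842 ± 0.101 in cKO (SD, n = 2). The difference of 0.016 was smaller than that between the pairs, 0.116, and had opposite signs within the pairs. The Actb ratio, of a gene that is itself an SRF target, was 2.37 ± 0.53 in het and 2.77 ± 0.49 in cKO, and higher in cKO within both pairs (3.119 against 2.748 and 2.428 against 2.002). For Actb too, the difference between the groups (0.399) was smaller than that between the pairs (0.718). The samples also differed in sex-linked transcripts, examined after the data were seen. The Y-linked gene Eif2s3y had a signal of 1485 in het_1210, 833.9 in het_1261, 1386 in Ko_1210 and 3.01 in KO_1261. Xist, expressed from the inactive X chromosome, had a signal of 62.6, 14338, 115.4 and 22802 in the same order. The array het_1261 thus held both Y-linked and Xist transcripts, whereas KO_1261 held Xist with Y-linked signal near background, and no label gives the sex or the pooling of embryos. Both genes were among those that passed with the block, and the call of Eif2s3y ended with the robust prior (adjusted p = 0.888). The Y-linked genes Kdm5d (0.26 and -7.59) and Uty (-0.08 and -4.45) also passed with the block. The 68 genes that fell thus include these Y-linked genes, whose fall rests on KO_1261.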

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

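The fit with the replicate number as a block, quantile scaling, median centring, the pseudocount, the filters, the variance models, the choice of probe set, the list tests and the left-out arrays were planned; the same choices combined with the block were added after the data were seen. Without the block, 0 genes passed in limma under every full-array setting, as in the fit reported first, and 0 to 2 genes and 0 to 5 probe sets passed with 1 array left out (2 genes without Ko_1210, 1 without KO_1261 and 0 without either het array, with the lone array of a group assumed to vary like the other group). With the block, 96 genes and 194 probe sets passed. Added to the block, quantile scaling gave 153 genes (96 of them shared with the 96) and 365 probe sets, median centring 52 (48 shared) and 109, the pseudocount of 32 gave 23 and 39, no filter 8 and 17, the stricter filter 45 and 91, the robust prior 50 and 84, the mean of a gene's probe sets 6 genes, leaving out _x_at and _s_at probe sets 75 genes, and a prior variance without trend 0 genes. The block with 1 array left out has no residual degrees of freedom, so within-pair differences stand in its place. The genes that differed by over 1.5-fold in every ratio numbered 53 after quantile scaling, 50 after median centring (17 higher and 33 lower, against 7 and 74), 49 with the pseudocount of 32, 1046 without the filter, 10 with the stricter filter and 15 at 2-fold. Causes other than fewer genes tested or fewer arrays were not tested.

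Srf was lower in every setting run and passed with the block (-3.93) except without the variance trend; the stricter filter removed it. Combined with the block its difference was -3.91 after quantile scaling, -3.81 after median centring, -3.39 with the pseudocount of 32, -3.93 with the robust prior or no filter, -3.42 as the mean of probe sets and -2.92 without _s_at probe sets. With 1 array left out it ranged from -4.30 to -3.56 and passed only without KO_1261. Of the 31 lists, 5 passed at first, 0 with an estimated correlation or by fry, 3 with no filter or the stricter filter, and 2 with the mean of probe sets. Median centring, and a prior variance without trend, each gave 6 lists (1 higher, 5 lower). Combined with the block, 7 passed after quantile scaling (3 higher, 4 lower) and 6 after median centring (1 higher, 5 lower). There were 3 with the pseudocount of 32, no filter or no variance trend, and 2 with the mean of probe sets or without _x_at and _s_at probe sets. The spinous list, with a median of -0.084, passed with the block and with the block and robust prior (-0.084). It also passed at -0.13 with the stricter filter and at -0.0033 after quantile scaling, each with and without the block. Its call with the block ended without _x_at and _s_at probe sets (adjusted p = 0.0625), with the pseudocount of 32 (0.0814), with the mean of probe sets (0.0978), with no filter (0.149) and without the variance trend (0.297). The G2 and M phase list did not pass with the mean of probe sets (0.153, and 0.0946 with the block), with the stricter filter (0.0531 and 0.073), with no filter and no block (0.0526), or with the block without _x_at and _s_at probe sets (0.0512) or variance trend (0.0707). Without the block, the melanocyte list did not pass with the mean of probe sets (0.369, median -0.19), quantile scaling (0.107) or no filter (0.277), nor the immune list with no filter (0.15). The endothelial list passed without the block with no variance trend (camera adjusted p = 0.0218), median centring (0.0462) and no filter (0.0448). With the block, the immune list passed after median centring (0.0386) and quantile scaling (0.0341). The melanocyte list did so without the variance trend (0.0367) and after median centring (0.0379). Median centring moved the median of the MRTF-SRF list to -0.095 (22 of 34 lower) and that of all tested genes from -0.02 to 0.10. It turned the spinous median to 0.038 (past the threshold with the block, where the median and the direction of the test differ) and that of actin filament assembly to 0.0032, with and without the block. The immediate early list passed at 0.28 with the block and quantile scaling and at 0.33 with the block and the stricter filter. The Actb ratio differed by 0.40 between the groups.

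Leaving out 1 array mixes the difference between the pairs into that between the groups, which by construction moves every gene that differs between the pairs. List medians then ranged from -0.28 to -0.17 for MRTF-SRF targets, -0.90 to 1.53 for immediate early genes, -0.21 to 0.036 for actin filament assembly, -0.030 to 0.12 for basal, -0.24 to -0.14 for spinous and -0.39 to 0.35 for granular genes, 0.025 to 0.19 for G2 and M phase genes and -0.28 to 0.024 for microtubule genes. For markers they ranged from -0.83 to -0.40 for fibroblasts, -0.81 to -0.13 for immune cells, -0.85 to -0.20 for melanocytes, -0.53 to -0.19 for endothelium, -0.45 to 0.15 for periderm, -0.12 to 0.19 for muscle and -0.36 to 0.036 for nerve. Of all lists, 5 to 8 passed: 5 without Ko_1210 (4 higher, 1 lower), 8 without KO_1261 (all lower), 7 without het_1210 (all lower) and 6 without het_1261 (4 higher, 2 lower). Genes whose sign turned ranged as follows: Atf3 -0.29 to 2.56, Ier3 -0.19 to 1.74, Zfp36 -0.52 to 3.25, Fos -0.41 to 1.30, Cxcl10 -0.23 to 3.11, Sprr1b -0.55 to 3.17, Lor -1.12 to 2.05, Ivl -0.55 to 1.51, Myl9 -1.37 to 0.04, Cfl1 -0.27 to 0.0093, Cdh1 -0.10 to 0.11, Itga6 -0.33 to 0.59, Itgb1 -0.26 to 0.76, Krt5 -0.45 to 0.20, Krt14 -0.45 to 0.30, Mki67 -0.12 to 0.23, Dcn -0.050 to 0.16, Eif2s3y -8.12 to 0.32 and Xist -3.14 to 4.68. With all arrays, with and without the block, Krt14 turned to 0.049 after median centring, 0.037 after quantile scaling and 0.29 as the mean of its probe sets, Dcn to -0.23 as the mean, Enox2 to -0.39 without _s_at probe sets and Tacc1 to -0.20 after quantile scaling. The median of the muscle markers turned to 0.078 after median centring, and that of the nerve markers to -0.14 with no filter and -0.0067 with the pseudocount of 32. The other genes compared between settings and the list medians given in the report kept their direction in the settings that gave a value. Kdm5d, Uty, Krtap13, Pde4b, Tnfaip3 and Ppp1r15a were not compared in this way. Signals near background, below the filter, limit what can be said of genes such as Flg.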

Other observations

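The tests of carry-over, handling and RNA quality below were chosen after the results were seen, except the comparison of the fibroblast markers between the pairs, whose outcome had not been seen. A pair of inflammatory chemokines, in no fixed list and named after their values were seen, rose in cKO with the block. Cxcl10, which attracts T cells, differed by 1.44 ± 0.17 (1.77 in the first pair and 1.11 in the second) and Ccl20, which attracts Langerhans cell precursors and T cells, by 2.11 ± 0.36 (2.89 and 1.33). Both calls held with the robust prior (adjusted p = 9.99e-06 and 0.00405). Both genes also differed strongly between the pairs: Cxcl10 had a signal of 468.4 and 4736 on the het arrays and 1600 and 10210 on the cKO arrays. Ccl20 had a signal of 21.6 on het_1210, below the filter, so its difference within the first pair is imprecise.

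The first pattern is the split of the immediate early genes, with Egr1, Egr2 and Egr3 lower and others higher in cKO. These genes respond to dissociation and sorting, so a weaker handling response in the cKO samples would lower the whole class by about as much as the Egr genes. All 18 tested members, the Egr genes included, had a median of 0.286 (SD 1.24) against -2.13 for the 3 Egr genes. The gap was 2.04 within the first pair (SD 1.401) and 2.81 within the second (SD 1.25). With 1 array left out the class median ranged from -0.90 without het_1210 to 1.53 without het_1261, and the gap to the Egr genes exceeded the SD each time (at least 2.02). The 3 Egr genes were picked for their fall, so the size of this gap does not decide. Of the 18 members 14 were higher and 4 lower, with class medians of 0.519 and 0.047 within the pairs. A fall of the whole class, as weaker handling would give, was thus not seen. Handling that acts on the Egr genes alone was not tested. A stronger handling response may still lie behind the rise of Dusp1, Zfp36, Jun, Atf3 and Ier3. Their median was 2.29 within the first pair and 0.25 within the second, so the rise rests largely on 1 pair of arrays. The 6 heat shock genes, which handling may also raise, had a median of 0.093 ± 0.084 (bootstrap SE over genes, as below) against 1.26 ± 0.15. These genes need not track the immediate early genes, however. From het_1210 to het_1261 Dusp1 went from 2122 to 14796. Hspa1a went from 1477 to 4808, but Hspa1b only from 13976 to 17179 and Hspb1 from 5547 to 5292. The explanations cannot be told apart with 1 array per group in each pair. Loss of Srf, whose ternary complexes act on the Egr genes, stays a hypothesis for their fall.

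The second pattern is the fall of Krt1, Krt10 and Sbsn, 3 of 16 tested spinous genes, of which 9 were lower and 7 higher. Fewer suprabasal cells carried through the sort would lower spinous and granular genes alike. Within the first pair the 21 granular and cornified genes had a median of 0.104 ± 0.197 (SD 0.956) and the 16 spinous genes -0.16 ± 0.17. Of the granular genes 11 were higher and 10 lower. Within the second pair the medians were -0.471 ± 0.172 (SD 0.487) and -0.10 ± 0.15, and 17 of the 21 granular genes were lower. That fall of the granular genes goes with fewer suprabasal cells in that pair, but the spinous genes as a list did not fall alike. Krt1, Krt10 and Sbsn fell more within the first pair (median -0.90) than within the second (-0.42). The pairs thus differed and the medians of neither pair decide for the spinous genes, and a change in early spinous cells alone was not tested. RNA quality also stays open. The Gapdh ratio differed by 0.0161 between the groups, less than between the pairs (0.116). The Actb ratio was higher in cKO within both pairs, by 0.40 on average, which was also less than between the pairs (0.718). Lower expression of spinous genes in cKO basal cells, carry-over and RNA quality cannot be told apart with 1 array per group in each pair.

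The third pattern is the fall of actin and other MRTF-SRF target genes together with fibroblast markers. Fibroblasts also express several of the target genes (actins, filamin, calponin) at high levels. If less dermal carry-over in the cKO samples were the cause, the target genes would fall more in the pair in which the fibroblast markers fell more. From the first to the second pair the fibroblast difference shrank by a median of 0.60 ± 0.20. That of the 5 passing target genes shrank by 0.325 ± 0.212, in 3 of the 5, while Actg1 and Flna fell more. Over all 34 tested target genes the change was -0.207 ± 0.077 (SD 0.75), a larger fall in the second pair for 22 of them. The medians of the passing genes and of the whole list thus had opposite signs, but the 5 passing genes were split and show no clear direction. These errors are over genes and hold no spread between arrays. Within the second pair the 34 target genes had a median of -0.200 ± 0.082 and the fibroblast markers -0.20 ± 0.08. The 5 passing genes, at -0.791 ± 0.188, lay below both, but they had been picked for their fall, so this does not decide. Carry-over and loss of Srf activity therefore cannot be told apart here, with 1 array per group in each pair.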
